A study of Homo sapiens with 21 samples.

How the data were processed

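The data were RNA sequencing libraries of U2OS and MCF7 cells, 21 samples in 7 groups of 3 per the labels. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and made into poly(A)-selected libraries. The submitters' processing notes name Salmon 1.10.1 for quantification, DESeq2 for testing and the hg38 genome. The DESeq2 version, the transcript annotation, any shrinkage of fold changes and the rule by which genes were kept are not given in the sources used here.

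Both tables analysed were the authors' own DESeq2 output and held no column of values for a single library. The mean normalised count per gene, a signal that is never negative, was deposited by the authors as a base mean, per the file headers. That it is a mean over samples after scaling by size factors was inferred from the DESeq2 output, and which samples entered it is not stated. Log2 fold changes were deposited by the authors for MYC-NU and MYC-U over GFP and for shCtrl against shKDM6A, the latter with a standard error on the log2 scale. The sample descriptions give a positive value of the MCF7 table as a change from shKDM6A to shCtrl, read as higher in shCtrl, and its sign was turned here so that positive means higher in shKDM6A, which puts KDM6A lower in the knockdown. Adjusted p-values were deposited by the authors for each comparison, and unadjusted p-values for the MCF7 table only. The Wald score of the MCF7 table, deposited by the authors, equals the log2 fold change divided by its standard error to within 2.6e-07, and its adjusted p-values equal a Benjamini-Hochberg adjustment of its p-values over 16917 genes to within 1.5e-05. Of the samples, 15 belong to the 5 groups of the 3 comparisons. The other 6, knockdown cells given HA-tagged KDM6A without or with its 3′UTR, were not analysed here.

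Because no values per library were at hand, no new test per gene was run, the depth per sample is unknown, and the authors' deposited adjusted p under 0.05 was counted, the test planned for such tables. The U2OS table gives no standard errors. Its unadjusted p-values were recovered by inverting the Benjamini-Hochberg adjustment (adjusted p times rank, divided by the number adjusted, with the highest rank for ties, which concern 51.3% of values in MYC-NU and 41.2% in MYC-U). A signed z and a standard error, the absolute log2 fold change divided by z, followed from them. The median recovered standard error was 0.073 in MYC-NU and 0.084 in MYC-U, and the median deposited one in MCF7 was 0.264. The U2OS table holds 12016 genes kept by an unstated rule, so that the number the authors adjusted over may be larger and the recovered p-values are then approximate. Among genes with a mean under 50, the recovered standard error lay below the Poisson counting error for 84 of 84 genes in MYC-NU and 91 of 93 in MYC-U, as it would if fold changes had been shrunk towards 0. Shrinkage is not stated by the submitters, and if it was applied the deposited U2OS fold changes understate the changes of low genes.

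The difference between MYC-U and MYC-NU was tested per gene as the difference of both log2 fold changes divided by the root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment over 11979 genes. As an alternative, a covariance of 0.5 times the mean squared standard error was subtracted for the shared GFP libraries. Tested on simulated data with the recovered standard errors of these 11979 genes and a shared control, the test as run called 85% of 100 genes with a log2 difference of 0.5, all of 100 with a difference of 1 and 0 unchanged genes. The alternative called 99% of the former and 14 unchanged genes. The simulated control had nearly the covariance that the alternative assumes, and no shrinkage was simulated, so that neither point was tested. Unchanged groups against a shared control were simulated 20 times for the overlap and correlation.

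A total of 26 gene lists and 5 marker sets of cell types were fixed before the data were examined. The mesenchymal or osteosarcoma set describes U2OS itself and the luminal epithelial set MCF7 itself, and each is foreign only to the other line. They were tested with limma 3.58.1 cameraPR in R 4.3.3 on the signed z or Wald score, two-sided, with a preset inter-gene correlation of 0.01. Adjustment was by Benjamini-Hochberg within a comparison over the lists with at least 3 measured members (29 in U2OS, 28 in MCF7). An estimated correlation needs values per library and could not be computed, so calls are given with a preset 0.05 beside it where they ended. On simulated statistics of 12000 genes, drawn independently of one another, 5 of 5 shifted lists of 40 and 0 of 21 others passed. This does not give the rate of false calls for lists whose members move together. The counts adjusted over the list alone used the recovered or deposited p-values of the list's members. A list's median was also placed among 10000 random lists of the same size matched on deciles of the mean. List members were matched by gene identifier or symbol, older symbols included.

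Named genes followed a rule fixed in advance: MYC or KDM6A, the 8 largest rises and falls among called genes with a symbol and a mean of at least 100, up to 4 called members by adjusted p from each list that passed and up to 2 from others fixed for that cell line, of which the text names part. For the difference, members of passing lists were taken by p whether called or not. Genes outside the rule are said to be chosen after their values were seen, or stand as members of a list whose count they explain. Gene positions are those of GENCODE 29 on GRCh38, matched by gene identifier. Alternatives covered the adjusted p threshold (0.01 and 0.1), a minimum change of 1.5-fold or 2-fold, a mean of at least 10 or 100, adjustment over all MCF7 genes with a p-value, genes with a symbol only, centring on the median, and for lists a correlation of 0.05, ranks, fold changes in place of the statistic, Fisher's exact test and lists without shared members. Python 3.11.15, numpy, pandas, scipy and matplotlib were used.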

Results

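RNA sequencing of poly(A)-selected RNA was used to ask how gene expression responds to a transcription factor or a chromatin regulator made from an mRNA with or without its own 3′ untranslated region (3′UTR). The series held 21 samples in 7 groups of 3. The 9 U2OS samples (a human osteosarcoma line) expressed GFP alone or MYC. MYC came from the coding sequence only (MYC-NU) or from the coding sequence followed by its full-length 3′UTR (MYC-U). The sample titles name these constructs GFP-MYC-NU and GFP-MYC-U, and the titles do not say whether GFP was fused to MYC. GFP-positive cells were sorted 24 hours after transfection. The 12 MCF7 samples (a human breast adenocarcinoma line) carried a scrambled hairpin (shCtrl) or a stable knockdown of KDM6A (shKDM6A), the gene of the histone H3 lysine-27 demethylase UTX. A further 6 of the MCF7 samples were knockdown cells given KDM6A back without or with its 3′UTR, and these were not analysed here.

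The values analysed were the authors' own comparisons, 1 table for each cell line, with no values for single libraries. The U2OS table listed 12016 genes and its mean normalised counts summed to 47337412. The MCF7 table listed 78277 genes, 42460 of them with a mean of 0, and its means summed to 21063918. The depth of single libraries is therefore unknown. The labels number 3 replicates in each group and do not say whether they were separate cultures, so that the p-values may measure technical spread.

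MYC-NU was compared with GFP to ask what MYC from a coding-sequence-only mRNA does to gene expression. In MYC-NU cells 987 genes were higher and 954 lower than in GFP cells at the authors' deposited adjusted p under 0.05, out of 11985 genes with an adjusted p. Fixed lists of MYC-activated targets, ribosome biogenesis genes, heat shock chaperones and MYC network partners were shifted upwards and that of cell cycle and DNA replication genes downwards, each with many members that did not pass. Most changes were small: the median absolute log2 fold change of the called genes was 0.29, and 162 of them changed by 1.5-fold or more.

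MYC itself (chromosome 8, 127735434 to 127741434, plus strand, GRCh38) had the highest mean of the U2OS table, 1201469 normalised counts, against 460991 for the next gene, MT-CO1, in the authors' deposited table. Its log2 fold change over GFP in the authors' deposited table was nevertheless only 0.49 in MYC-NU (adjusted p = 4.14e-05) and 0.17 in MYC-U (adjusted p = 0.146). The MYC transcript therefore did not separate the MYC-U libraries from those labelled GFP only, and the directions below rest on the labels.

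Among genes with a symbol and a mean of at least 100, to which the largest changes given for each comparison are limited, the largest rise in MYC-NU was that of HSPA6, a stress-inducible HSP70 chaperone (chromosome 1, 161524540 to 161526910), with a log2 fold change of 4.42, or 21.3-fold, in the authors' deposited table (adjusted p = 2.61e-49). HSPA1A and HSPA1B, which code for the same inducible HSP70 protein, followed at 2.18 and 1.91 in the authors' deposited table. These neighbouring genes are nearly identical in sequence, so that the split of reads between them is uncertain. Next in the authors' deposited table came FOSB at 1.85, RGS16 at 1.46, ZNF296 at 1.38, IL12A at 1.32 and ANKRD37 at 1.27. The largest falls in the authors' deposited table were those of GP6 at -1.24, TSPAN2 at -0.96, DNAJB4 at -0.88 and ZNF44 at -0.83, followed by ARRDC3, FAM111A, PLD1 and the mitotic kinesin KIF18B, between -0.83 and -0.79.

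Among 58 measured MYC-activated targets, 27 rose, 2 fell and 29 did not pass, and adjusted over the list alone 34 rose and 3 fell. The list was shifted upwards (limma cameraPR, adjusted p = 1.31e-13). Examples in the authors' deposited table were EXOSC5, a subunit of the RNA exosome, at a log2 fold change of 0.84, NOP56, a core protein of box C/D small nucleolar ribonucleoproteins, at 0.52, and GNL3 at 0.50. Of 53 genes of RNA polymerase I and ribosome biogenesis, 27 rose and none fell, with a median log2 fold change of 0.19 (cameraPR adjusted p = 1.32e-11; 32 rose adjusted over the list alone). GTPBP4 (0.35), RIOK1 (0.38) and NOL10 (0.29) led that list by adjusted p in the authors' deposited table. The 77 cytosolic ribosomal protein genes showed a small common shift: the list passed (median 0.06, adjusted p = 0.00934) although no single member did, and 76 of 77 had a positive log2 fold change. That call ended at a preset correlation of 0.05 (adjusted p = 0.149).

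In the MYC network, 5 of 13 measured partners rose and none fell (cameraPR adjusted p = 1.51e-05; 6 rose adjusted over the list alone). They included MNT, MXI1 and MXD1, repressors that compete with MYC for its partner MAX, with log2 fold changes of 0.95, 0.70 and 0.33 in the authors' deposited table, and MAX itself at 0.44.

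Of 40 cell cycle and DNA replication genes, 17 fell, 4 rose and 19 did not pass (cameraPR, downwards, adjusted p = 8.53e-04; 18 fell and 4 rose adjusted over the list alone). The falling members included TOP2A, the topoisomerase of mitotic chromosomes, at -0.79 and the mitotic kinase CDK1 at -0.78 in the authors' deposited table. The G1/S regulators CCNE1 and CDC25A rose by 0.58 and 0.48 on the log2 scale in the authors' deposited table.

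Of 20 heat shock chaperones, 4 rose and 1, DNAJB4, fell (cameraPR, upwards, adjusted p = 7.88e-05; 6 rose and 2 fell adjusted over the list alone). The list had a median of 0.06 and a mean of 0.42, drawn up by the 3 HSP70 genes, and its call ended on ranks and by Fisher's exact test. Integrated stress and unfolded protein response genes did not pass (2 of 29 rose and 4 fell, 4 and 5 adjusted over the list alone, adjusted p = 0.831). Of 18 immediate early genes, 6 rose and 1 fell (adjusted p = 6.06e-04; 7 and 1 adjusted over the list alone). The neuronal activity gene ARC rose by 1.07 and JUN fell by 0.35 on the log2 scale in the authors' deposited table. Of 16 NF-kB and inflammatory cytokine genes, 5 rose (adjusted p = 0.00116; 6 adjusted over the list alone), led in the authors' deposited table by TNFAIP3 at 0.77 and the macrophage growth factor CSF1 at 0.51. Of 24 measured HOX genes, a list fixed for the MCF7 comparison, 10 rose and 1 fell (adjusted p = 8.88e-05; 11 and 1 adjusted over the list alone), with HOXC13 at 0.62 and HOXA11 at 0.51 in the authors' deposited table.

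Further lists passed in MYC-NU at the preset correlation of 0.01 and not at 0.05. Of 25 p53 pathway and apoptosis genes, 6 rose, among them PLK3 (0.62) and the pro-apoptotic BBC3 (0.73) in the authors' deposited table, with adjusted p = 0.00585, and 0.0555 at 0.05. Of 21 hypoxia response genes, 6 rose and 2 fell, with VEGFA at 0.48 in the authors' deposited table, adjusted p = 0.0228, and 0.101 at 0.05. Of 33 extracellular matrix and mesenchymal genes, 10 fell and 2 rose, with adjusted p = 0.00587, and 0.0671 at 0.05. Collagen genes COL5A2 (-0.70) and COL1A1 (-0.45) fell while SNAI1, a repressor of epithelial genes, rose by 0.91 in the authors' deposited table. Of 14 interferon-stimulated genes, 5 fell and 2 rose, with TRIM22 at -0.66 in the authors' deposited table, adjusted p = 0.0228, and 0.0829 at 0.05. Adjusted over the list alone, the counts were 6 risen for p53, 6 risen and 3 fallen for hypoxia, 2 and 11 for extracellular matrix and 2 and 5 for interferon.

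Not all MYC-linked lists passed. Of 25 MYC-repressed genes, 4 rose and 4 fell (4 and 5 adjusted over the list alone), and the list showed no common shift (adjusted p = 0.604, median -0.01, mean 0.03). ARRDC4 and BTG1, listed there as repressed, rose by 0.79 and 0.47 on the log2 scale in the authors' deposited table. Of 30 nucleotide and polyamine synthesis genes, 4 rose, among them PPAT at 0.31 in the authors' deposited table, and the list did not pass (adjusted p = 0.27). Of 6 luminal epithelial markers none passed. The mesenchymal marker set was shifted downwards (4 of 9 fell, adjusted p = 0.0228), a call that ended at 0.05 (adjusted p = 0.0671) and on ranks. That set describes U2OS itself and shares members such as COL1A1 with the extracellular matrix list. Of 3 embryonic kidney line markers 2, SALL1 and WT1, rose (0.23 and 0.35 in the authors' deposited table, set adjusted p = 0.0211). The embryonic kidney call ended by Fisher's exact test (adjusted p = 0.0738).

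**Figure D1:**
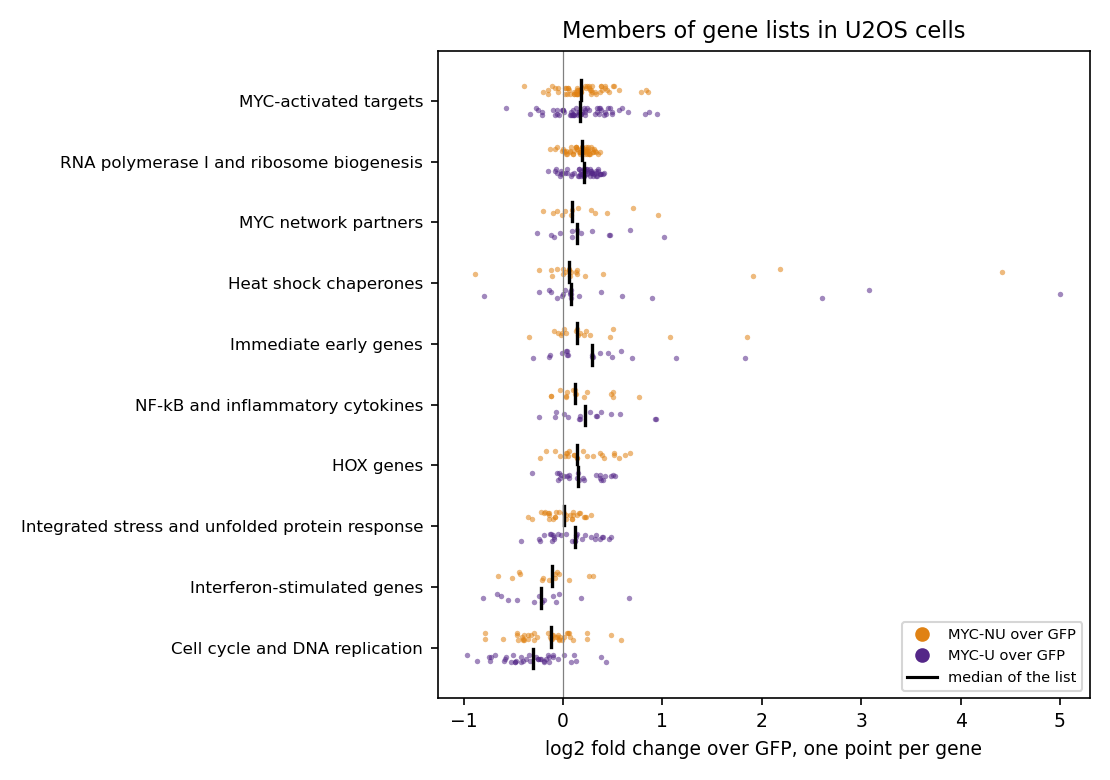
Log2 fold changes over GFP of the members of 10 gene lists in U2OS cells, as deposited by the authors, with MYC-NU in orange and MYC-U in purple, one point per gene and a bar at each list's median. The ribosome biogenesis list has a median of 0.19 in MYC-NU and 0.22 in MYC-U, and the cell cycle list lies at -0.12 and -0.30.

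The corresponding comparison of MYC-U with GFP asked what MYC from the 3′UTR-containing mRNA does. In MYC-U cells 1375 genes were higher and 1590 lower than in GFP cells at the authors' deposited adjusted p under 0.05, out of 12001. The median absolute log2 fold change of the called genes was 0.32, and 332 changed by 1.5-fold or more. The inducible HSP70 genes again led the rises in the authors' deposited table, with HSPA6 at a log2 fold change of 5.00, HSPA1A at 3.07 and HSPA1B at 2.61. The matrix metalloprotease MMP3 (1.93), FOSB (1.83), RGS16 (1.51), ZNF296 (1.37) and the muscle ubiquitin ligase FBXO32 (1.32) came next in the authors' deposited table. The largest falls in the authors' deposited table were those of GP6 (-1.65), PLAC8 (-1.23), PLD1 (-1.09), FAM111A (-1.09), MAP1A (-1.06), PDLIM1 (-1.05), TSPAN2 (-1.02) and TOP2A (-0.96).

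Ribosome assembly genes rose in MYC-U as well, 29 of 53 with none falling (cameraPR adjusted p = 2.95e-09; 36 adjusted over the list alone), and 26 of them had also risen in MYC-NU. Of the MYC-activated targets 28 of 58 rose and 5 fell (adjusted p = 1.60e-08; 31 and 6 adjusted over the list alone). Those that fell included the replication helicase genes MCM4 and MCM5 and the mitotic kinase gene PLK1. Of 13 MYC network partners 6 rose (adjusted p = 4.18e-05; 7 rose and 1 fell adjusted over the list alone), with MNT at 1.02 and MXD1 at 0.47 in the authors' deposited table.

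Of the 40 cell cycle and replication genes, 25 fell and 2 rose in MYC-U (cameraPR adjusted p = 5.81e-09; 28 and 2 adjusted over the list alone), and all 17 that fell in MYC-NU were among them. AURKB, the kinase of the chromosomal passenger complex, stood at -0.59, E2F2 at -0.74 and CDK1 at -0.87 in the authors' deposited table. Heat shock chaperones rose in 7 of 20 cases and fell in 1 (adjusted p = 2.75e-07; 7 and 1 adjusted over the list alone). Immediate early genes rose in 10 of 18 cases and fell in 1 (adjusted p = 1.30e-04; 10 and 1 adjusted over the list alone), with KLF10 at 0.45 and NR4A1 at 0.69 in the authors' deposited table. Among NF-kB and cytokine genes 6 of 16 rose (adjusted p = 1.30e-04; 8 adjusted over the list alone), with IL11 at 0.94 and LIF at 0.49 in the authors' deposited table. HOX genes rose in 9 of 24 cases and fell in 1 (adjusted p = 0.00363; 9 and 1 adjusted over the list alone), led by HOXA9 at 0.42 in the authors' deposited table. Interferon-stimulated genes fell in 6 of 14 cases and rose in 1 (adjusted p = 0.00665; 8 and 2 adjusted over the list alone). PARP9 stood at -0.66 and OAS3, an RNase L activator, at -0.62 in the authors' deposited table, while the exonuclease gene ISG20 rose by 0.66.

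The p53 and apoptosis list passed in MYC-U (7 of 25 rose and 1 fell, the same adjusted over the list alone, adjusted p = 0.016) but not at a preset correlation of 0.05 (adjusted p = 0.1). Extracellular matrix genes did not pass as a list (12 of 33 fell, 4 rose, adjusted p = 0.0758), nor did hypoxia genes (6 of 21 rose, 2 fell, adjusted p = 0.0687) or ribosomal protein genes (1 of 77 rose, adjusted p = 0.0758). Of 30 nucleotide and polyamine synthesis genes 5 fell and 2 rose, and the list did not pass (cameraPR adjusted p = 0.556). RRM2 and DHFR, at -0.48 and -0.34 in the authors' deposited table, were among those that fell. The mesenchymal markers (4 of 9 fell, adjusted p = 0.00856) and embryonic kidney line markers (2 of 3 rose, adjusted p = 0.00613) moved as in MYC-NU. Both marker calls ended by Fisher's exact test (adjusted p = 0.0812 and 0.118). CD68, the only measured leukocyte marker, rose by 0.39 on the log2 scale in the authors' deposited table.

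MYC-U and MYC-NU were then set against each other, since the design compares the templates with and without the 3′UTR. The responses ran in the same directions: 857 genes were higher and 806 lower in both, and none was called with opposite signs. Independent lists of those sizes would share 113.3 and 126.6 genes. Across the 11979 genes tested in both, which are not independent replicates, the fold changes correlated with Pearson's r = 0.907 and Spearman's rho = 0.885. Both comparisons use the same GFP libraries, and unchanged groups simulated against a shared control gave r = 0.504. They gave no gene called in both, but unchanged groups yield almost no calls at all, so this is no measure of the overlap. The simulated noise was drawn gene by gene and cannot mimic GFP libraries that differ as a whole. The covariance was 0.0393 against 0.00335 simulated, a difference of 0.036. Without values for single libraries the controls could not be split, and part of the excess overlap may come from them.

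Fold changes were larger in MYC-U. Over the 3243 genes called in either comparison the total least squares slope of MYC-U on MYC-NU was 1.32, against 1.01 in simulations with equal effects, and the median ratio over the 1663 genes called in both was 1.21, against 1.05 simulated with equal effects. By gene, the difference passed for 1 gene, TRIML2, a tripartite-motif family member (chromosome 4, 188091273 to 188109603). It stood at a log2 fold change of 0.37 in MYC-NU and 1.30 in MYC-U in the authors' deposited table, a difference of 0.93 with a recovered standard error of 0.195 (adjusted p = 0.0226). Of the 11979 genes, 341 had an unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give in an exact test. This test adds both variances as if independent and is conservative, so that the count cannot be read against that share. It does not say whether further genes differ. With the shared control taken into account, 72 genes passed, 50 of them higher and 22 lower in MYC-U.

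**Figure D2:**
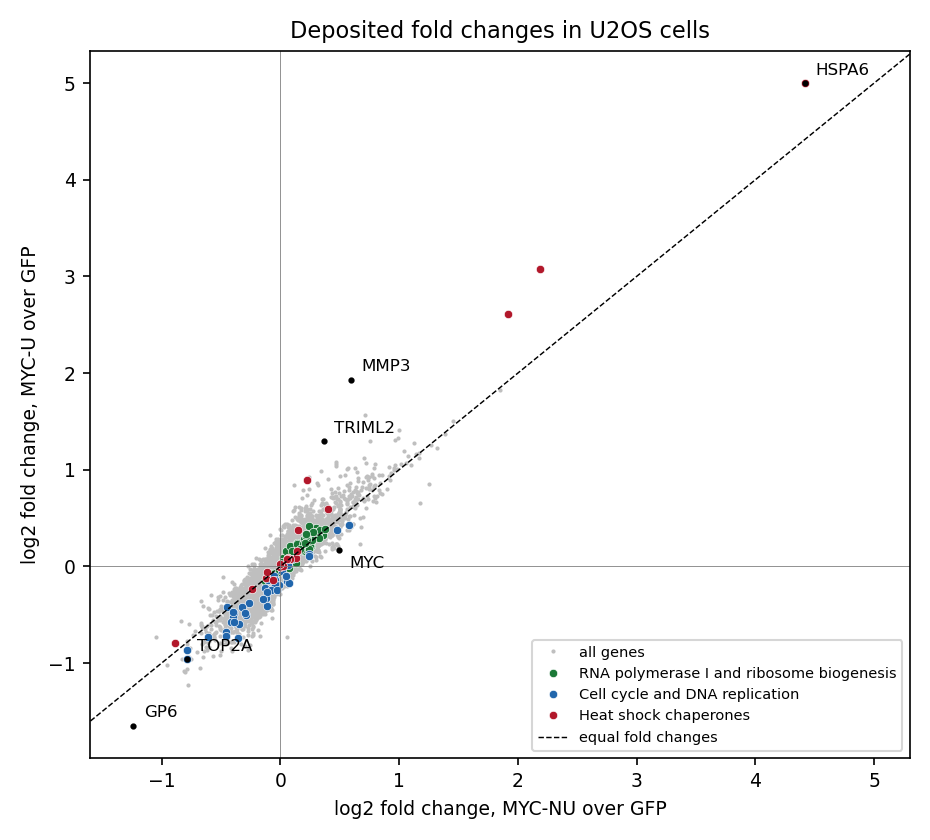
Log2 fold change over GFP in MYC-U (vertical axis) against that in MYC-NU (horizontal axis), one point per gene as deposited by the authors, with 3 gene lists in colour and a dashed line where both are equal. TRIML2 lies at 0.37 and 1.30, and 39 of the 40 cell cycle genes lie below the line.

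Lists were then tested on the difference. Cell cycle and replication genes were lower in MYC-U than in MYC-NU as a list (median difference -0.15, cameraPR adjusted p = 2.42e-12), with 1 of 40 members above 0 and no member passing singly, also when adjusted over the list alone. Differences of MCM4, E2F1 and E2F2 were -0.17, -0.24 and -0.39 with recovered standard errors of 0.0723, 0.103 and 0.172. Nucleotide and polyamine synthesis genes were lower too (median -0.06, adjusted p = 2.60e-04), with DUT, the dUTPase, at -0.27 and DHFR, the target of methotrexate, at -0.20, and none of 30 passed, although DUT passed with the shared control taken into account. Integrated stress and unfolded protein response genes were higher in MYC-U than in MYC-NU (median 0.07, adjusted p = 2.04e-05), a list that did not pass over GFP with either template (adjusted p = 0.831 in MYC-NU and, with 8 of 29 risen and 2 fallen, 0.117 in MYC-U). Their differences were 0.38 for PPP1R15A, a phosphatase subunit that acts on eIF2α, and 0.41 for the transcription factor gene DDIT3 (CHOP), and 2 of 29 passed adjusted over the list alone. Heat shock chaperones were higher as a list (median 0.02, mean 0.17, adjusted p = 2.60e-04), carried by DNAJB1 at 0.67, HSPA1B at 0.70 and HSPA1A at 0.89, and 3 of 20 passed adjusted over the list alone. With the shared control taken into account, PPP1R15A, DDIT3, DNAJB1, HSPA1B and HSPA1A passed singly as well. NF-kB genes (median 0.05, adjusted p = 0.0149, IL11 at 0.43) and immediate early genes (median 0.08, adjusted p = 0.034, KLF10 at 0.22) were also higher, with no member passing, but their calls ended at a preset correlation of 0.05 (adjusted p = 0.084 and 0.133). Fold changes were larger in MYC-U in general, so a list shifted over GFP with both templates can shift further for that reason alone. The mean log2 fold changes over GFP in MYC-NU and MYC-U were 0.421 and 0.588 for heat shock chaperones. They were 0.189 and 0.277 for NF-kB genes and 0.263 and 0.335 for immediate early genes. The list test does not separate such general scaling from a difference of the list itself. MYC-activated targets did not separate the templates (median -0.01, adjusted p = 0.693), nor did ribosome biogenesis genes (median 0.02, adjusted p = 0.158). The MYC transcript itself was at -0.32 with a recovered standard error of 0.135 and did not pass.

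In MCF7 cells, shKDM6A was compared with shCtrl to ask what loss of KDM6A changes. KDM6A (chromosome X, 44873177 to 45112602) was lower in the knockdown, with a log2 fold change of -0.45 and a standard error of 0.208 in the authors' deposited table, which leaves 73.2% of the control level (95% interval 55.2 to 97.1%). It did not pass (p = 0.0307 and adjusted p = 0.524 in the authors' deposited table), and 990 genes had a smaller p, so that the targeted transcript separated the groups weakly. Between the groups 65 genes were higher and 66 lower in shKDM6A at the authors' deposited adjusted p under 0.05, out of 16917. The called genes had a median absolute log2 fold change of 1.23. Interferon-stimulated genes were shifted downwards as a list, with 5 of 33 falling, and PTBP2, a splicing regulator of neurons, rose.

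PTBP2 (chromosome 1, 96721665 to 96823738) was 3.43-fold higher in shKDM6A, a log2 fold change of 1.78 with a standard error of 0.2 in the authors' deposited table (adjusted p = 5.22e-15). Its paralog PTBP1, chosen after its values were seen, stood at -1.05 with a standard error of 0.18 in the authors' deposited table (adjusted p = 9.78e-06). Among genes with a symbol and a mean of at least 100, the other large rises in the authors' deposited table were those of TNIK, a kinase of the Wnt pathway, at 2.22, the GABA receptor subunit GABRB2 at 1.83, the chaperone gene CLGN at 1.6, the prostaglandin receptor PTGER3 at 1.54, CAV1 at 1.44, PCDH9 at 1.40 and SLIT2 at 1.38. The largest falls among the same genes in the authors' deposited table were those of IFI6 at -2.22, the cytokine IL20 at -1.86, SUMF1, which activates sulfatases, at -1.62, ISG15 at -1.6, the potassium channel KCNN4 at -1.56, LOXL2 at -1.50, PDCD4 at -1.49 and L1CAM at -1.49. Standard errors of these genes lay between 0.2 and 0.4 on the log2 scale.

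**Figure D3:**
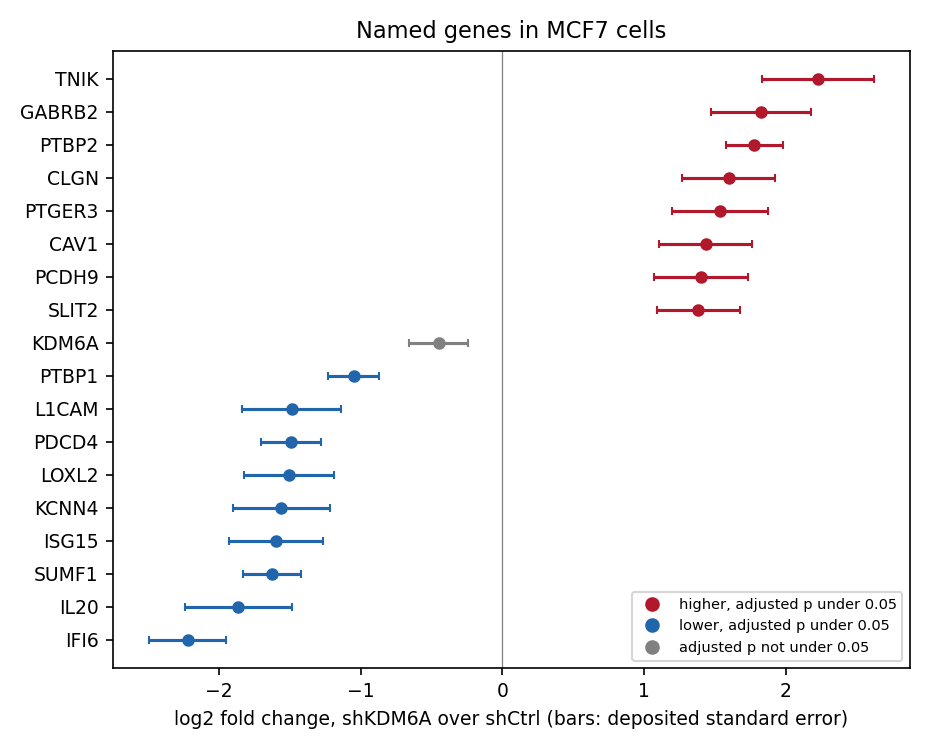
Log2 fold change of shKDM6A over shCtrl in MCF7 cells for KDM6A, PTBP1 and the 8 largest rises and falls among genes with a mean of at least 100, with bars for the standard error in the authors' deposited table and grey for a gene that did not pass. KDM6A lies at -0.45, PTBP1 at -1.05 and PTBP2 at 1.78.

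Of 33 measured interferon-stimulated genes, 5 fell, none rose and 28 did not pass, and adjusted over the list alone 13 fell and 1 rose. The list was shifted downwards (median log2 fold change -0.46, cameraPR adjusted p = 6.77e-15). IFI6 and ISG15 were joined by IFI27 at -2.52, with a mean of only 47.8 normalised counts, and IFITM1, a membrane protein that restricts virus entry, at -1.0 in the authors' deposited table. Of 25 extracellular matrix and mesenchymal genes, 2 fell and none rose (median -0.32, adjusted p = 2.48e-04; 3 fell adjusted over the list alone), a call that ended by Fisher's exact test. The genes that fell were the collagen cross-linking enzyme LOXL2 and the fibronectin receptor subunit ITGA5, at -1.50 and -1.20 in the authors' deposited table. The smaller mesenchymal marker set lay the other way and did not pass (5 of 7 positive, 1 risen, median 0.20, adjusted p = 0.162), nor did the luminal epithelial markers (1 of 12 risen, adjusted p = 0.531). Both measured leukocyte markers lay lower (median -1.36), as did the 1 erythroid marker, but none was called over all genes, and neither were the 2 embryonic kidney line markers. Adjusted over the list alone, 1 of 2 leukocyte and 1 of 2 embryonic kidney line markers fell. These 3 sets were too small to test.

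A further 9 lists passed in shKDM6A at the preset correlation of 0.01 with no member called over all genes, and none of these calls held at 0.05, where adjusted p ran from 0.206 to 0.282. Canonical histone genes lay higher (median 0.20, adjusted p = 0.00965, 4 of 38 risen adjusted over the list alone), as did integrated stress genes (median 0.18, adjusted p = 0.0443, 1 of 29 risen adjusted over the list alone) and Polycomb complex genes (median 0.10, adjusted p = 0.0443). Cytosolic ribosomal protein genes lay lower (median -0.10, adjusted p = 0.00965), as did glycolysis genes (-0.23), epithelial genes (-0.24) and MYC-repressed genes (-0.12), each with adjusted p = 0.0223. The p53 list (-0.06, adjusted p = 0.0443) and MYC-activated targets (-0.08, adjusted p = 0.046) passed narrowly. Of these lists only MYC-repressed genes had another member passing when adjusted over the list alone, 1 of 27 that fell.

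Estrogen response, luminal and basal breast gene lists did not pass. Of 41 estrogen response genes 4 rose and 1 fell (adjusted p = 0.133; 4 and 2 adjusted over the list alone), including CXCL12 at 1.13 and IGFBP5 at 1.34 in the authors' deposited table. ERBB4 was the 1 luminal gene of 21 that rose (0.98 in the authors' deposited table, list adjusted p = 0.706) and CAV1 the 1 basal gene of 19 (list adjusted p = 0.642). Genes of the UTX and COMPASS-like complex (0 of 21, adjusted p = 0.539) and HOX genes (0 of 12, adjusted p = 0.529) held no called member. The estrogen response gene that fell was HSPB8, also a heat shock chaperone, by 0.95 on the log2 scale in the authors' deposited table. Outside these lists the tubulin gene TUBB3 fell by 0.88 on the log2 scale in the authors' deposited table.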

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

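All the tests of technical explanations below were chosen after the result was seen, as was the comparison of recovered z, whereas the tests of the difference between MYC-U and MYC-NU were planned. These results stood out because the response differed between the templates by a test of the difference itself. The median difference, MYC-U minus MYC-NU, was -0.148 on the log2 scale for cell cycle and DNA replication genes, with 39 of 40 members lower in MYC-U, and -0.058 for nucleotide and polyamine synthesis genes. It was 0.0691 for integrated stress and unfolded protein response genes, 0.0201 for heat shock chaperones, 0.0523 for NF-kB and cytokine genes and 0.0802 for immediate early genes, and both of these calls ended at a preset correlation of 0.05 (adjusted p = 0.084 and 0.133), that of NF-kB genes also on ranks. Fold changes were larger in MYC-U in general, and the list test does not separate that from a difference of the list itself. Cell cycle genes can move together, so that the 40 members are not independent observations, and none of them passed singly. How far they move together could not be estimated without values for single libraries. TRIML2 differed by 0.93 and was the only gene to pass singly under the test that treats both variances as independent.

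The first pattern is that fold changes over GFP were larger in MYC-U. More MYC RNA in the MYC-U libraries is argued against, because the MYC log2 fold change was lower in MYC-U, by -0.32 with a recovered standard error of 0.135. That holds only as far as the MYC values can be trusted, which the next pattern puts in doubt. Weaker shrinkage of the MYC-U fold changes as the whole cause would leave the recovered z alone. The median ratio of recovered z was 1.12, above 1, which argues against shrinkage alone in these libraries. The spread of 0.0082 is over resampled genes and does not measure variation between libraries, which could also raise z. Equal effects simulated 0.946, but this value cannot decide. Its standard errors come from the same fold changes, so that larger MYC-U fold changes lower it. The ratio in fold changes was 1.21 against 1.05 simulated. Whether shrinkage adds a part was not decided, since the simulations use standard errors recovered from the same fold changes. The presence of the 3′UTR and a different protein level remain untested, since no protein values were at hand.

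The second pattern is that MYC had the highest mean of the U2OS table but small fold changes over GFP. Shrinkage alone is argued against, because 4186 genes had a smaller adjusted p than MYC in MYC-U against GFP, and shrinkage of fold changes does not alter p. At face value, and if the mean covers the 3 groups equally, the GFP libraries would hold a mean of 1019047 normalised MYC counts. MYC reads in libraries labelled GFP only may therefore be part of the cause, for instance through a MYC-containing plasmid, sequence carried over between libraries or an exchanged sample. Values for single libraries would be needed to separate these, and no biological explanation was tested.

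The third pattern is that PTBP1 was lower and PTBP2 higher in shKDM6A, both beyond their standard errors, while KDM6A did not pass. Reads shared between the paralogs are argued against, since 0 % of the 31-mers of the smaller transcript set were shared (7287 in PTBP1 and 13019 in PTBP2). An effect of the hairpin on PTBP1 that does not go through KDM6A stays open: the log2 fold change of PTBP1 was lower than that of KDM6A by a difference of -0.598 with a standard error of 0.275, and the hairpin sequence is not given in the sources used here. Loss of KDM6A itself also stays open, and the groups cannot be told apart on this point because each hairpin defines its group.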

How the results depend on the processing

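The tests on recovered z and those without HSPA6, HSPA1A and HSPA1B were chosen after seeing the data. No paired analysis was possible because neither table holds values for single libraries. For the same reason the comparisons planned with other count tools and normalisations, a filter on low counts, another pseudocount, a replicate block and leaving out replicates were not run, nor was a count of other splits of the samples. Readjustment of raw p was not run for U2OS, whose table gives none, and the alternatives for HA-KDM6A were not run because those samples were not analysed here.

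Of the summary values under an alternative, 43 stayed within their limit and 21 moved, and none reversed. With an adjusted p under 0.01 the genes called were 1094 in MYC-NU (611 higher, 483 lower), 67 in shKDM6A, 956 in both MYC templates and 0 for the difference between them. An adjusted p under 0.1 gave 202 genes in shKDM6A. A change of at least 1.5-fold left 162 genes in MYC-NU, 332 in MYC-U and 146 in both, and 2-fold left 21 and 45. These shifts follow from the stricter or looser thresholds. Taking the shared control into account called 72 genes for the difference (50 higher and 22 lower in MYC-U), because it takes a smaller variance. Testing the difference only in genes called in either comparison gave 2, because fewer genes were adjusted over.

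The slope of MYC-U on MYC-NU, 1.32, was 1.22 by ordinary least squares, 1.21 as a median ratio and 1.12 on recovered z, all above 1. Equal effects simulated 1.05 for the median ratio and 0.946 on z, where standard errors recovered from the same fold changes lower the simulated value. The cause of the spread between these values was not tested. Without the 3 HSP70 genes it was 1.33. Pearson's r stayed between 0.901 and 0.908.

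Of 15 list calls in MYC-NU, 9 were made at a correlation of 0.05. In shKDM6A 11 lists passed, against 2 at a correlation of 0.05, 2 by Fisher's exact test, 2 on log2 fold changes and 6 with a mean of at least 100. The lists that passed by Fisher's exact test were not the same as those at 0.05. The higher correlation widens the variance of every list, and Fisher's test reads called members alone. The cause was not tested for the other settings. For the difference between templates 6 lists passed, between 4 and 7 under the other camera settings and 0 by Fisher's test, which had 1 called gene to work with. Single list calls were lost in 65 cases and kept in 197. Single named genes kept their direction and their side of the threshold in 500 cases, among them MYC in MYC-U and KDM6A, which were not called. Of these cases, 170 came from centring and 169 from a mean of at least 100. Both settings could change little, since the medians lay between -0.012 and 0.0064 and nearly all named genes had such a mean. When an adjusted p under 0.01 was asked, 161 were kept and calls were lost in 9. Without the depth of single libraries, what depth limits cannot be stated beyond 31 called genes of shKDM6A that had a mean under 100.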

Other observations

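No hypothesis was tested in this part, and the genes in it were chosen after their values were seen, apart from the list members and the alternative that takes the shared control into account, which was planned.

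With the shared control taken into account, the 22 genes lower in MYC-U than in MYC-NU included FAM111B at a log2 difference of -0.47, the kinetochore gene SPC24 at -0.46, TUBB at -0.33, the primase subunit gene PRIM1 at -0.29, DUT at -0.27 and the replication kinase gene CDC7 at -0.26. The 50 genes higher in MYC-U included MMP3 at 1.34, GDF15 at 0.68, DNAJB1 at 0.67, the matrix genes COL6A3 at 0.49 and NID1 at 0.40, DDIT3 at 0.41, PPP1R15A at 0.38, SALL1 at 0.37 and KDM6B, the paralog of KDM6A, at 0.36. In simulated data this test called 14 genes without a difference, beside 99% and 100% of 100 genes each with differences of 0.5 and 1. That simulation used nearly the covariance that the test assumes, and no shrinkage. The 14 are therefore no error count for the genes named here.

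In sterol synthesis HMGCS1 rose and SREBF1 fell with either template, at log2 fold changes of 0.31 and -0.41 in MYC-NU and 0.51 and -0.46 in MYC-U in the authors' deposited table. The sterol list as a whole did not pass (adjusted p = 0.537 and 0.766).

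In shKDM6A the smallest adjusted p was that of ARL10 (3.78e-27), with a log2 fold change of 5.87 and a standard error of 0.50 in the authors' deposited table, at a mean of only 67.6 normalised counts. Among estrogen response genes PGR and TFF3 also rose, by 1.33 and 1.1 on the log2 scale in the authors' deposited table.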
